A study of Coprinopsis cinerea with 7 samples.

How the data were processed

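Genomic DNA of Coprinopsis cinerea oidia was extracted with a plant DNA kit and made into libraries with an Illumina TruSeq kit, per the labels' protocols. The submitters' processing notes list Bismark 0.6.4, Bowtie 0.12.7 and edgeR, without a version for edgeR or the role of each tool. How reads were extended, deduplicated or filtered, and the genome build, are not given in the sources used here.

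The authors deposited 2 tables of read counts per 300 bp window, whose names refer to MEDIPS, an R package for enrichment sequencing. The columns used are headed as counts and hold whole numbers per window, and whether these are raw is not stated. The name of the second table refers to multiple mapped and unique reads, and its column names carry a suffix whose meaning is not given in the sources used here. Windows with no reads at all in the primary table (231) had a median summed input count of 731 in the multi-mapped table, and no window held more than 1071 counts there, against 162928 in the primary table. Both tables also hold the authors' edgeR log2 fold changes, deposited as input over IP, and their adjusted p-values, which equal the deposited p-value times the number of windows with one (Bonferroni). These 2 kinds of column were read only to count the authors' calls, of which 3910 of 3917 in the primary table and 2684 of 3864 in the multi-mapped table were called higher here too. A further 8 columns of per-sample RPKM values were not used.

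Each count column names IP or input by its header, or, for the IP columns of the multi-mapped table, by lacking the word input. No label carries the tags 1_1 and B_1, so the columns were taken as 2 replicates per group without a tie to the biological replicate numbers. The 5 IP libraries appear as 2 columns, and whether technical replicates were merged is not stated. P-values here measure only the spread between these columns. The planned test between biological replicates of IP, and fits with each library as its own column, need separate columns and were not run.

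Windows higher or lower in IP were called with edgeR 4.0.16 (R 4.3.3): TMM scaling, a quasi-likelihood test of 2 IP columns against 2 inputs, a total of at least 10 counts, and a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken from the quasi-likelihood F statistic. Called higher windows were merged across gaps of at most 1 window, and regions of at least 3 called windows counted. A region's value is the mean CPM of its summed windows per group, with the SD of the 2 columns and no separate test. Gene counts are sums over windows whose midpoint lies in the gene. The tests, thresholds, lists, naming rule and most alternatives were fixed before the data were examined. Named regions are the 10 longest, the 10 with the highest mean window log2 fold change among those higher in both IP columns, and the 5 lowest regions of at least 2 lower windows. Named genes are the highest genes past the threshold with at least 50 counts and the same direction in both columns (12, of which at most 4 without a product name), the 5 lowest, and up to 4 called members per list.

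Gene positions came from a RefSeq gene table of assembly CC3 with 13657 genes, 13497 of them on the 13 chromosomes and 13250 with a window midpoint. As no build is named for the window tables, the match was settled from the data. On each of the 13 chromosomes the correlation of input counts with gene cover was highest with no shift between table and genes (r of 0.118 to 0.225, against at most 0.0786 in size at shifts beyond 10 windows, up to 300 windows each way). In 98 of 112 segments of 300 kb the best shift was within 1 window. Coordinates printed are those of the window tables. The gene table gives locus tags and gene types but no product names, so lists defined by product words (such as transposon-related genes, DNA methyltransferases, histones and ribosomal proteins) were not analysed here, 4 highest genes are named in place of 12, and the tRNA list was the 1 list run, with no adjustment over lists needed. Of 255 tRNA genes 87 hold a window midpoint. Exon positions and CpG content were not analysed here, since no genome sequence was used.

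Positions were tested by shifting the calls circularly along each of the 13 chromosomes (the sequences of at least 500 kb) 10000 times. For the densest bin, groups of called windows were placed at random 10000 times per chromosome, and a last bin with far fewer windows than the others (under 50% of their median) was left out. The tRNA list was tested with Fisher's exact test and with 10000 circular shifts of the calls along the gene order, using scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9.

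The tests were tried on simulated counts with 200 changed windows or genes among unchanged ones. Each was drawn independently, with a single dispersion shared by IP and input columns. The rates below therefore do not cover the noisier IP columns, or the many clustered and mostly higher calls, of the real data. For windows of the primary table (119450), 64.0% of 1.5-fold, 100% of 2-fold and 100% of 4-fold increases and 96.0% of decreases to 0.5-fold were recovered, with 9 false calls. For windows of the multi-mapped table (120536) the recovered shares were 84.0%, 100%, 100% and 96.0%, with 11 false calls, and for genes of the primary table (13231) 100% of each, with 8 false calls. Of 200 simulated sets of randomly placed regions 4.50% had p under 0.05 in the circular-shift test of chromosome ends. The median count per window was 750 and 466 in the IP columns and 275 and 282 in the inputs of the primary table, and 177 and 134 in the IP columns and 213 and 208 in the inputs of the multi-mapped table, where counting error is the larger limit on precision. The common biological coefficient of variation was 8.53% in the primary and 4.23% in the multi-mapped table.

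The alternatives tried were DESeq2 size factors, library totals, the Wald test of DESeq2 1.42.0, no count filter or a total of at least 50, the header tag as a block, an adjusted p under 0.01, at least 2-fold, the multi-mapped table, each column left out in turn, windows summed in fives, other merging gaps, distances and bins, and overlap by any base for genes.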

Results

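Coprinopsis cinerea, the ink cap mushroom used as a laboratory model of basidiomycete development, was studied at the stage of oidia, its asexual spores. The assay, CMS-seq, maps 5-hydroxymethylcytosine (5hmC), an oxidation product of 5-methylcytosine made by TET/JBP enzymes. Bisulfite turns 5hmC into cytosine-5-methylenesulfonate (CMS), and an antiserum against CMS then pulls down the DNA fragments that carry it. The labels describe 7 libraries from 2 biological replicates, namely 5 anti-CMS immunoprecipitations (IP; 3 of the first biological replicate and 2 of the second) and 2 inputs. The deposited tables hold 2 IP columns and 2 input columns, tagged 1_1 and B_1, so the comparison is of 2 IP columns with 2 inputs. The genome was divided into 120537 windows of 300 bp on 13 chromosomes and 54 supercontigs, 36.2 Mb in all. In the primary table the summed window counts were 106176723 and 67181684 for the IP columns (1_1 and B_1) and 36059418 and 36233140 for the inputs. In a second table, named for multiple mapping and called the multi-mapped table here, they were 24990768 and 19994333 for IP and 28735765 and 27600179 for input. Window counts of the IP pair had a Pearson r of 0.976 in the primary table and those of the input pair 0.992, across windows, which are not independent replicates. The chi-square per degree of freedom was 9.69 for the IP pair and 1.89 for the input pair, so both pairs differed by more than the sampling noise of independent reads. This covers counting error only, since amplified copies of a fragment also raise it. The multi-mapped table gave 1.502 for the IP pair and 0.916 for the inputs, which differed by less than the sampling noise.

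The first question was where the anti-CMS antiserum enriched DNA over input. Enrichment was found at 10457 of 119450 tested windows (8.75%), and 764 windows (0.640%) were lower in IP. The median enriched window was 1.53-fold higher, 2152 windows were at least 2-fold higher and 755 at least 4-fold higher, against 528 and 5 in the multi-mapped table. Of the lower windows 0 were at least 2-fold lower by edgeR's quasi-likelihood test and 0 by DESeq2, against 16 at an unadjusted p under 0.05 in edgeR. DESeq2 called 212 lower windows in all. The number of lower windows rests on the scaling: with library totals in place of TMM factors the median log2 fold change of all windows moved from -0.01 to -0.16, and 6554 windows were higher and 7533 lower, a 46.5% share of higher calls against 93.2%. Each left-out column moved these counts, but such fits take their spread from the other group's 2 columns alone. The inputs alone set it without an IP column, and the noisier IP columns alone without an input. Without IP 1_1 there were 17485 higher and 10984 lower windows, without IP B_1 14813 and 5789, without input 1_1 5805 and 49, and without input B_1 4580 and 157. The authors' deposited table of the same windows held 3917 windows higher in IP and 2 lower at their adjusted p under 0.05. Their multi-mapped table held 3864 higher and 0 lower. Their adjustment is the stricter Bonferroni one, against Benjamini-Hochberg here, so these counts and those above are at unlike thresholds.

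Enriched windows formed 1183 regions of at least 3 called windows, with a median length of 1800 bp and a total of 7.62% of the sequence, and 90 regions were longer than 5000 bp. Library totals gave 788 regions, and leaving out input 1_1 or input B_1 gave 702 or 561. The longest region lay on chromosome 1 at 3346201 to 3361500, where 46 of 51 windows were enriched across 6 gene models (CC1G_00600 and CC1G_00602 to CC1G_00606). It held 1067 ± 110 CPM (TMM-scaled counts; SD, n = 2) in IP and 572 ± 18.5 (n = 2) in input, a 1.87-fold difference. The first 12900 bp of chromosome 10 formed the next longest region, 1.68-fold higher (1510 ± 58.2 against 900 ± 66.6 CPM; SD, n = 2 per group). The first 11400 bp of chromosome 4 were 1.65-fold higher, and the first 12600 bp of supercont3.16, where gene models were not analysed here, 1.49-fold. On chromosome 9 a region at 1524301 to 1534500 overlapped CC1G_20178 and CC1G_15189 and was 2.51-fold higher (773 ± 62.4 against 308 ± 22.9 CPM). Another at 750001 to 761400 covered 7 gene models from CC1G_02415 to CC1G_02421 and was 1.82-fold higher. Chromosome 7 held a region at 2505901 to 2515500, over CC1G_05876 to CC1G_05880, where all 32 windows were called and IP was 2.36-fold higher (979 ± 160 against 415 ± 9.03 CPM), and one at 616201 to 626100 (1.71-fold). The remaining long regions, on chromosome 12 at 1031401 to 1041900 and on chromosome 4 at 3168601 to 3178500, were 1.63-fold and 1.48-fold higher.

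**Figure D1:**
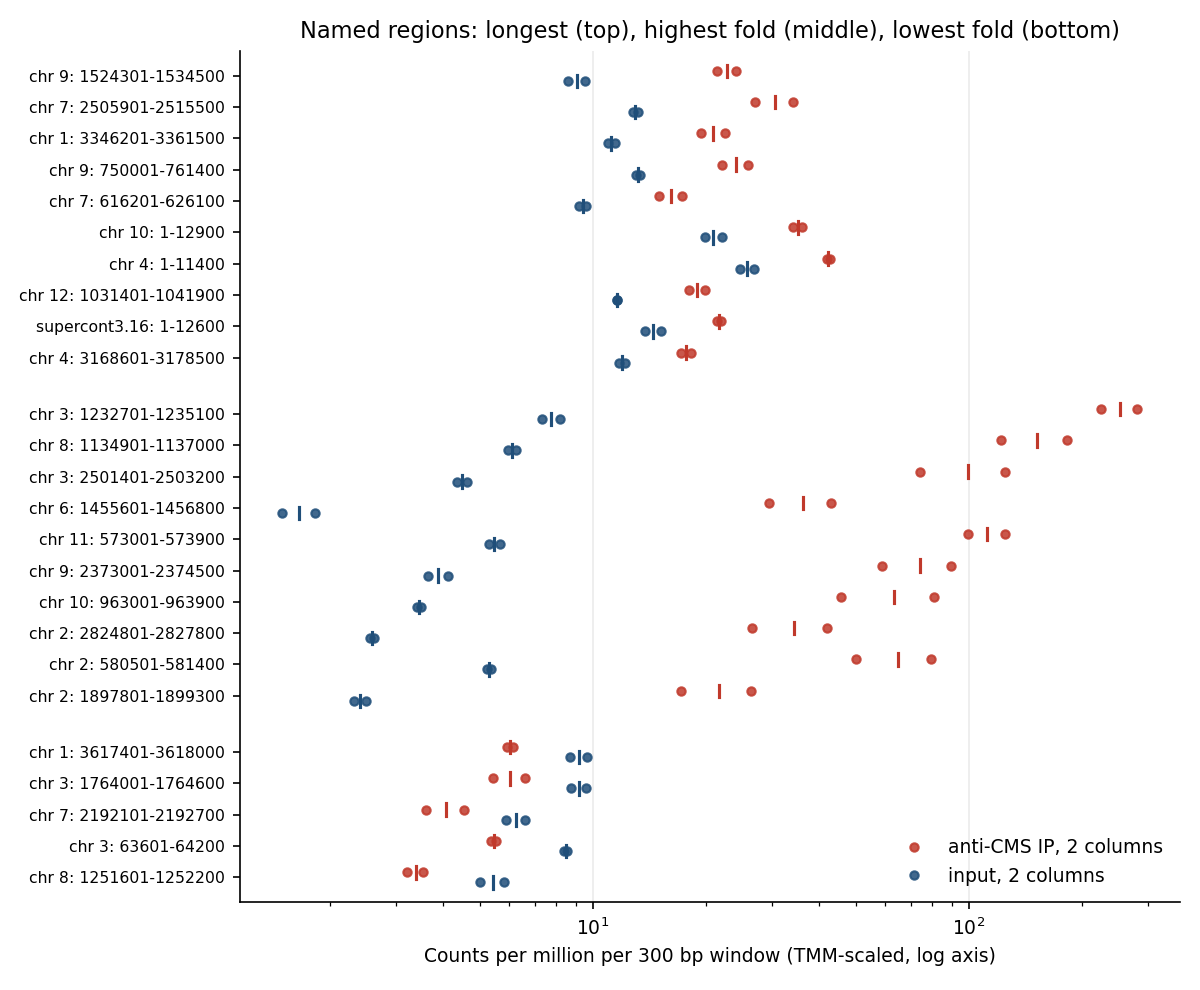
CPM (TMM-scaled counts) per 300 bp window on a log axis in the 25 named regions, with 1 point per column (2 anti-CMS IP, 2 input) and a line at each group's mean. The longest regions are 1.48-fold to 2.51-fold higher in IP, the highest-fold regions 9.02-fold to 32.6-fold, and the bottom 5 regions lower in IP, by the primary table's counts scaled with TMM.

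The 10 regions with the highest mean window fold spanned 900 to 3000 bp and are given here by the fold of their summed counts. Of these 10, the highest by that measure lay on chromosome 3 at 1232701 to 1235100 and overlapped CC1G_14146. It held 2020 ± 315 CPM (SD, n = 2) in IP against 61.9 ± 4.80 (n = 2) in input, 32.6-fold more. A region on chromosome 8 at 1134901 to 1137000, over CC1G_11689, was 24.9-fold higher (1064 ± 298 against 42.7 ± 1.44 CPM). A second region on chromosome 3, at 2501401 to 2503200, touched no gene model and was 22.2-fold higher. Regions that also touched no gene model lay on chromosome 6 at 1455601 to 1456800 (21.9-fold), chromosome 11 at 573001 to 573900 (20.5-fold), chromosome 9 at 2373001 to 2374500 (19.2-fold), chromosome 10 at 963001 to 963900 (18.3-fold) and chromosome 2 at 580501 to 581400 (12.3-fold). Chromosome 2 held another region at 2824801 to 2827800 over CC1G_09167 (13.3-fold) and one at 1897801 to 1899300 over CC1G_13941 (9.02-fold). The same 10 regions were 1.48-fold to 2.46-fold higher in the multi-mapped table. Among the enriched windows IP column B_1 exceeded 1_1 in 77.7%, and in 743 of the 755 windows with at least 4-fold enrichment.

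Of the 5 named regions lower in IP, each 600 bp long, the lowest, on chromosome 8 at 1251601 to 1252200 within CC1G_02916, held 6.75 ± 0.461 CPM (SD, n = 2) in IP and 10.8 ± 1.15 (n = 2) in input, a ratio of 0.624. The other four lay on chromosome 3 at 63601 to 64200 (CC1G_09613, ratio 0.644) and 1764001 to 1764600 (CC1G_01990, 0.654), chromosome 7 at 2192101 to 2192700 (CC1G_05724, 0.652) and chromosome 1 at 3617401 to 3618000 (CC1G_00698, 0.658). In the multi-mapped table their ratios were 0.709 to 0.915, and both windows of the regions on chromosome 8, on chromosome 1 and at 1764001 on chromosome 3 were called lower by edgeR's quasi-likelihood test. Of the region on chromosome 7 it called 1 window, and of that at 63601 on chromosome 3 it called 0.

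The 2 tables come from one series and carry the same tags, but whether their columns hold the same libraries is not stated. They were compared by overlap without a test, since shared libraries would share their chance values. The multi-mapped table gave 8437 higher and 984 lower windows of 120536 tested and 1009 regions. Counting its inputs, which agree within sampling noise, as 1 sample left 5204 higher windows, a setting chosen after seeing the data. Of the 10457 windows enriched in the primary table, 6725 (64.3%) were also called in the multi-mapped table, where 724 would be shared by independent lists, and the Jaccard index was 0.553. All 10457 had a log2 fold change above 0 in the multi-mapped table. Windows called in both had a median log2 fold change of 0.70 in the primary and 0.45 in the multi-mapped table. Of the lower windows 277 were called in both.

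Along the chromosomes, enriched windows were unevenly spread. In the primary table chromosome 6 had the highest share of tested windows called (13.2%), followed by chromosomes 9 (12.7%) and 12 (12.3%), while chromosome 9 (10.98%) led chromosome 6 (10.3%) by the multi-mapped table's calls. The lowest shares in the primary table were those of chromosomes 5 (4.76%), 1 (5.06%) and 8 (5.08%). The supercontigs, short unplaced pieces of the assembly, had 31.2% (341 of 1094 windows) in the primary and 21.1% in the multi-mapped table. Leaving out short last bins, the densest 50 kb bin of each chromosome held between 33.1% enriched windows (chromosome 8, 2050001 to 2100000) and 54.5% (the last bin of chromosome 13, 950001 to 983100). Further dense bins were found on chromosome 4 at 2450001 to 2500000 (49.7%), chromosome 9 at 200001 to 250000 (47.9%) and chromosome 10 at 1 to 50000 (47.9%). On 13 of 13 chromosomes the densest bin lay above the 95th percentile of 10000 random placements of the same groups of called windows. On 0 of 13 it lay above the highest of these placements. By the multi-mapped table's calls, 12 of 13 lay above the 95th percentile. Observed shares are of tested windows and placed shares of all windows, and overlapping placements count once. The placed shares are therefore somewhat low. The densest bin was at the same place in both tables on 10 chromosomes. Within 50 kb of a chromosome end 15.6% of tested windows were enriched (666 of 4268) against 8.28% elsewhere (p = 0.00940, two-sided circular-shift permutation test, 10000 shifts). The share rose to 26.1% within 20 kb (permutation p = 0.0001, the smallest that these shifts can give). For the multi-mapped table, 10.3% of windows within 50 kb were enriched against 6.73% elsewhere, which did not pass the same permutation test (p = 0.127), while 16.0% within 20 kb (permutation p = 0.00200) and 11.2% within 100 kb (p = 0.00890) passed.

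**Figure D2:**
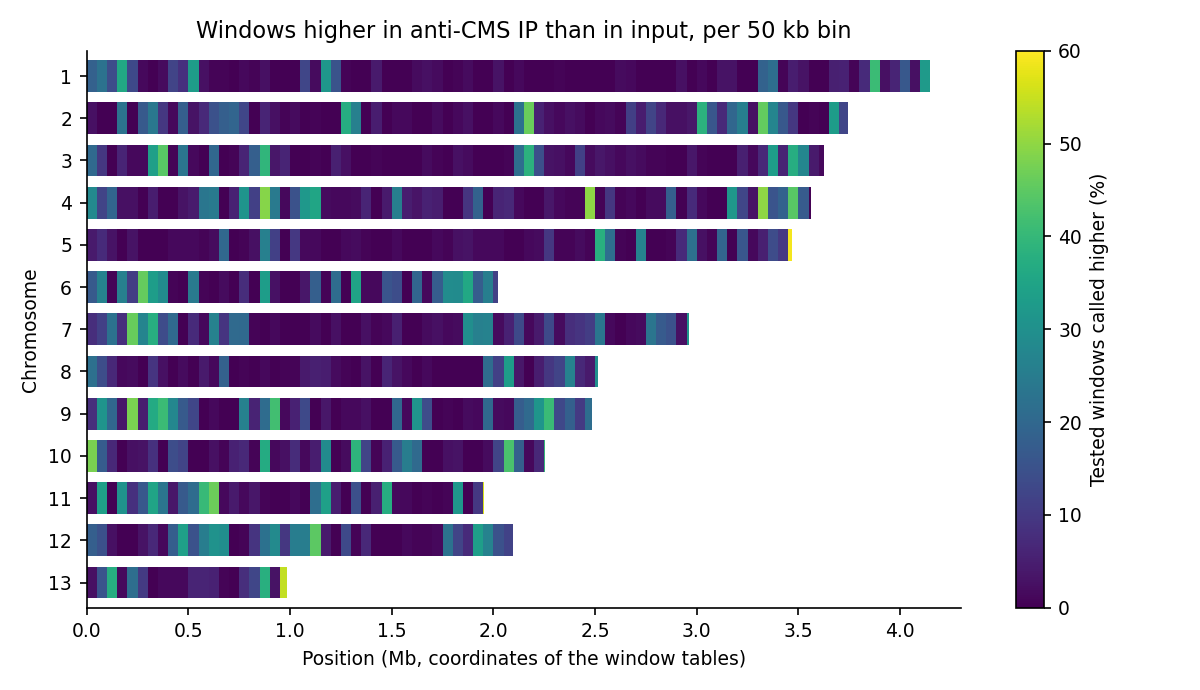
Percentage of tested 300 bp windows called higher in anti-CMS IP (colour) in consecutive 50 kb bins of the 13 chromosomes, primary table, against position in megabases. Dense bins include the ends of chromosomes 5 (58.9% of 56 windows), 11 (56.2% of 16 windows) and 13 (54.5%) and the start of chromosome 10 (47.9%), while chromosomes 1, 5 and 8 have long stretches near 0.

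Gene by gene, 1482 of 13231 tested genes (11.2%) were higher in IP and 72 lower, with 194 at least 2-fold higher, against 31 in the multi-mapped table. The count of lower genes was 1279 with library totals (1307 higher), 1236 without IP 1_1, 329 without IP B_1, 10 without input 1_1 and 90 without input B_1. The highest was CC1G_14887 on chromosome 7, with 4212 ± 1500 CPM (SD, n = 2) in IP and 11.7 ± 0.546 (n = 2) in input (log2 fold change 8.49 ± 0.26 SE, edgeR quasi-likelihood adjusted p = 1.21e-07). A single window of it, 2253901 to 2254200, held 156436 and 162928 counts in the IP columns and 194 and 219 in the inputs. CC1G_13941 on chromosome 2 was 156-fold higher, from an input of 0.139 ± 0.0259 CPM. CC1G_02422 on chromosome 9 was 74.0-fold higher (log2 6.21 ± 0.21 SE) and CC1G_11689 on chromosome 8 was 26.3-fold higher (log2 4.72 ± 0.17 SE). These 4 genes were called in the multi-mapped table too, at 2.97-fold, 1.56-fold, 1.94-fold and 1.79-fold in the same order. The lowest gene was CC1G_05768 on chromosome 7 (log2 -0.91 ± 0.25 SE, edgeR adjusted p = 0.0407), followed by CC1G_06086 (-0.46 ± 0.12), CC1G_05441 (-0.45 ± 0.09), CC1G_13357 (-0.44 ± 0.07) and CC1G_01440 (-0.42 ± 0.11). CC1G_05768 held only 282 counts in total over 5 windows. Its values were 1.34 ± 0.355 CPM in IP and 2.60 ± 0.0686 in input (SD, n = 2 per group). By the multi-mapped table, CC1G_05768, CC1G_06086 and CC1G_05441 were not called lower (log2 -0.03, -0.15 and -0.13; edgeR adjusted p of 0.853, 0.542 and 0.419), and CC1G_13357 and CC1G_01440 were. The calls of CC1G_05768 and CC1G_06086 also ended with the DESeq2 Wald test (log2 -0.94 and -0.46; adjusted p of 0.103 and 0.0577) and without input 1_1 (log2 -0.89 and -0.43; edgeR adjusted p of 0.142 and 0.349). Without input B_1 those of CC1G_05768, CC1G_06086, CC1G_05441 and CC1G_01440 ended (edgeR adjusted p of 0.102, 0.163, 0.0619 and 0.297), with log2 fold changes of -0.94, -0.50, -0.44 and -0.33. Both tables called 1311 genes higher and 28 lower. Independent lists would share 164 or 165 higher genes, but the tables may hold the same libraries, so a large overlap was likely in advance.

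Genes for transfer RNA were the one list fixed in advance that the gene table's types could define. Of 87 tRNA genes tested, 13 (14.9%) were higher in IP (14 adjusted over the list alone). Among the other genes 11.2% were higher (odds ratio 1.396, Fisher's exact test p = 0.303, two-sided; circular-shift permutation p = 0.341). At the threshold of at least 2-fold the difference passed: 6 of the 87 were called against 1.43% of the other genes (odds ratio 5.11, Fisher's exact test p = 0.00174; circular-shift permutation p = 0.00350). Neither test matched genes on their number of windows. Other genes can sum several windows, which can average a high fold away, so this difference cannot be tied to tRNA genes as such. The strongest were CC1G_20165 on chromosome 8, at 28.1 ± 7.38 CPM (SD, n = 2) in IP and 8.55 ± 0.554 (n = 2) in input, 3.28-fold, and CC1G_20001 on chromosome 1, 2.59-fold. CC1G_20061 on chromosome 3 was 2.51-fold higher and CC1G_20152 on chromosome 7 was 2.44-fold higher. All 4 were called higher in the multi-mapped table as well, at 1.69-fold to 1.93-fold. Each rests on 1 window, and windows are longer than a tRNA gene, so the values also cover its flanks.

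The position of enriched windows relative to genes was compared after the data had been seen. Outside annotated genes 13.1% of tested windows on chromosomes were enriched (5353 of 40829), against 6.14% inside genes (4763 of 77527), a ratio of 2.13 (p = 0.0001, two-sided circular-shift permutation test, the smallest that 10000 shifts can give). The ratio was 2.14 in the multi-mapped table (10.5% against 4.92%; the same p). The share grew with distance from the nearest gene, from 8.36% within 300 bp to 35.7% at 4001 to 8000 bp, and was 25.2% beyond 8000 bp. The multi-mapped table's share grew from 7.48% within 300 bp to 16.0% at 1001 to 2000 bp and lay between 15.0% and 18.7% farther out. Of the 1141 regions on chromosomes, 282 (24.7%) touched no gene model. Lower windows lay the other way, with 644 of 758 (85.0%) inside genes, where shifted calls gave 494 or 495 on average (permutation p = 0.0001).

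**Figure D3:**
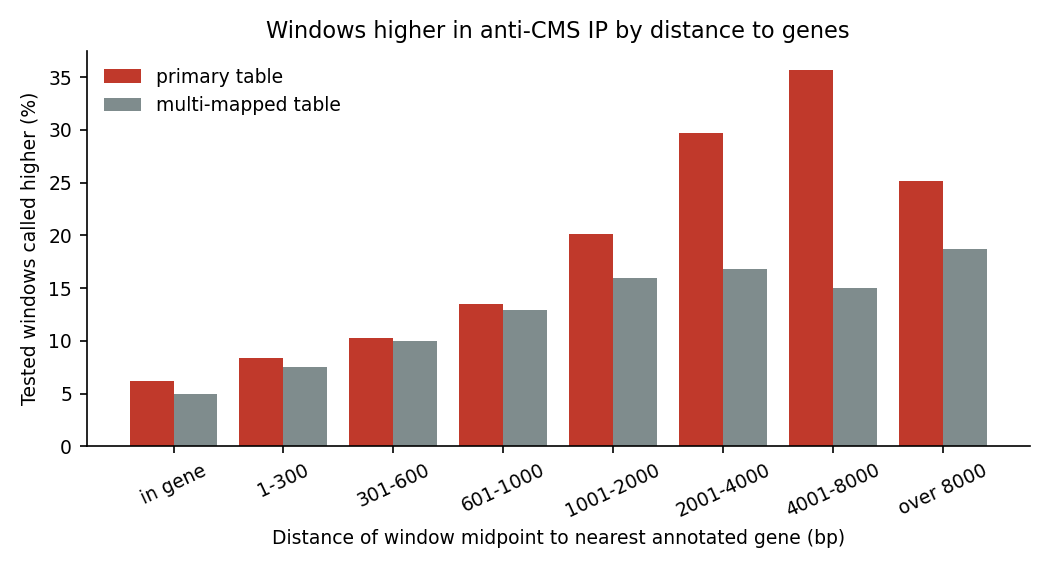
Percentage of tested 300 bp windows called higher in anti-CMS IP (bars from 0) by the distance of the window's midpoint to the nearest annotated gene, in base pairs, for the primary and the multi-mapped table. The share is 6.14% and 4.92% inside genes and reaches 35.7% in the primary table at 4001 to 8000 bp, where the multi-mapped table has 15.0%.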

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

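The multi-mapped table with a block, with its inputs as 1 sample, with the densest bins and with 20 kb and 100 kb from chromosome ends, the placements of runs of adjacent windows, the scaling of genes by the windows' library sizes and the alternatives for shared calls were chosen after seeing the data. The counts of higher windows, regions and genes stayed within 1.5 times under DESeq2 size factors (10374, 1182 and 1462), the DESeq2 Wald test, both count filters and the multi-mapped table. Library totals gave 6554 higher windows, 7533 lower windows and 788 regions, since they move all log2 fold changes down. The DESeq2 Wald test called 212 lower windows, and the cause was not tested. An adjusted p under 0.01 gave 5922 higher and 52 lower windows, 717 regions and 4017 windows shared by both tables. At least 2-fold left 2152 higher and 0 lower windows (0 also by DESeq2, and 16 at an unadjusted p under 0.05 in edgeR), 302 regions and 194 genes. Windows summed in fives gave 3491 higher (fewer, wider windows were tested), and merging across 5 windows 731 regions. With each column left out in turn, and the lone column assumed to vary like the other group, higher windows ranged from 4580 to 17485, lower windows from 49 to 10984, regions from 561 to 1483 and genes from 1271 to 2079, and the cause of this range was not tested. With the inputs of the multi-mapped table counted as 1 sample there were 5204 higher windows and 644 regions, in a fit with fewer samples.

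The header tags pair 2 IP with 2 input columns, but no label says what they share. Columns with the same tag had correlated deviations (r = 0.155 in the primary table, 0.0614 in the multi-mapped one, across windows). With the tag as a block there were 14868 higher and 4635 lower windows, 1212 regions, and 1797 higher and 596 lower genes, and by the multi-mapped table's counts 7940 higher and 981 lower windows, 939 regions and 1494 higher genes. The share of enriched windows near chromosome ends passed at 20 kb and 100 kb, and in the multi-mapped table it was 10.3% and did not pass at 50 kb (circular-shift permutation p = 0.127) but passed at 20 kb and 100 kb (permutation p of 0.00200 and 0.00890). Densest bins above the highest placement were found on 2 chromosomes with bins of 100 kb, on 2 with runs of adjacent windows placed, and in the multi-mapped table on 0 with bins of 50 kb and 1 with bins of 100 kb. The tRNA odds ratio, 1.396 (p = 0.303), was 1.54 (p = 0.0145, Fisher's exact test) with any overlap of window and gene, where the circular-shift permutation p was 0.0672, 5.11 at 2-fold or more and 1.54 in the multi-mapped table. None of the 25 named regions and 13 named genes reversed direction in the alternatives run. Apart from the longest regions, all were chosen for their fold in these same counts, the tRNA genes as the highest called members of their list. All of these but the tRNA genes were also chosen for a shared direction. That left little room for a reversal. The 8 genes named as higher stayed called in 15 settings each, and the 5 named as lower lost the call in at least 1 setting each. By the multi-mapped table's counts, 23 of the 25 regions moved by more than the spread between columns. Fits of all 7 libraries as separate columns, leaving out single technical libraries and the comparison with CpG content were not run.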

Other observations

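The tests in this part were chosen after the results were seen, except that the bounds for the tests by input depth and within genes near chromosome ends were written before their values were computed. Enriched genes lay next to one another. On the 13 chromosomes 927 pairs of neighbouring genes were both higher in IP, against an expected 196 or 197, and the highest of 1000 permutations of the gene order within chromosomes gave 239. The multi-mapped table had 982 such pairs. Single enriched regions crossed several gene models, as given above, and permuting the gene order breaks such regions up. An excess of pairs was thus likely in advance and adds little to the regions. The longest run had 23 genes, on chromosome 4, from CC1G_04084 to CC1G_04107. The multi-mapped table's longest run had 16, also on chromosome 4, from CC1G_14519 to CC1G_04158.

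Windows that lose input reads in the primary table relative to the multi-mapped one were more often enriched. Where the log2 ratio of the input shares (primary over multi-mapped) was under -0.5, 31.8% of 7684 tested windows were higher in IP, against 7.17% of the others, and by the multi-mapped table's counts 23.5% against 5.70%. These windows were 6.43% of those tested and held 23.4% of the calls (permutation p = 0.0001 in both tables, the smallest that 10000 circular shifts can give). The share was 44.4% between ratios of -2 and -1 and 7.15% under -4, where the median summed input was 7 counts in the primary table. By the multi-mapped table, the windows under -4 had a median of 1119 counts, and 14.7% were called. Most windows with a ratio under -0.5 lie outside annotated genes, for example 81.8% of those between -4 and -2.

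The preference for sequence outside genes may reflect the spread of the modified base or a property of the assay. Input depth was weighed first. In the multi-mapped table the share called outside genes was above 1.2 times that inside in 5 of 5 quintiles of input count, with ratios from 1.56 to 2.94, which argues against depth as the whole cause. Reads that map to several places were weighed next. Without windows under the ratio of -0.5 the primary table still gave 1.68 times the share outside genes, which argues against these windows as the whole cause, though the ratio fell from 2.13. Base composition, CpG content and the annotation's missing gene models stay open, and no biological explanation was tested, since IP and input come from the same kind of cells.

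The 755 windows at least 4-fold higher in the primary table had a median fold of 6.51 there and 2.06 in the multi-mapped table. A candidate explanation is that reads stacked at few positions in the IP columns of the primary table. The prediction, written after the data were seen, was that stacking alone would leave under 50% of these windows called in the multi-mapped table. Of them 95.6% (722) were called there. A bound on counts can lower a stacked window's fold without ending its call, and the tables may share libraries. The share called thus cannot tell stacking from enrichment. A ceiling on counts per window in the multi-mapped table would leave windows with a mean IP count under 500 with most of their fold. The 526 such windows kept a median of 0.394 of the primary log2 fold, which speaks only to a ceiling on a window's total. A limit on reads per position could lower folds at any count, so this split cannot weigh it. How far stacked or amplified reads at few positions raise the primary folds, such as the 378-fold of the window at 2253901 on chromosome 7 (2.97-fold in the multi-mapped table), stays open, as do different libraries behind the columns of each table, and no biological explanation was tested.

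The excess near chromosome ends may come from more repeated and gene-free sequence there. Within genes and at input ratios of at least -0.5 the share called within 50 kb of an end was still 2.18 times that elsewhere (12.1% against 5.55%). This was within the spread of circular shifts (275 windows against a mean of 202, permutation p = 0.203). The shifts also move calls from outside genes onto these windows, so their mean is not the rate within genes. The test thus does not hold sequence content fixed, and content and position cannot be told apart by it.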
